A study of Mus musculus with 16 samples.

How the data were processed

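Gene expression was measured in primary hepatocytes cultured from male C57Bl/J mice, with 16 competitive 2-colour hybridizations on Agilent 44K mouse arrays. Per the labels, cells were kept in Williams Medium E, left untreated or given 100 µM SQ1 or 30 µM pravastatin 48 h after plating, and lysed after 48 h of treatment. SQ1 is squalestatin 1, an inhibitor of squalene synthase. Its dose is given as labelled; squalestatins act at nanomolar doses, so that the unit is uncertain. Each array carried RNA of treated cells in 1 dye and of untreated control cells in the other, 8 arrays for SQ1 and 8 for pravastatin. The treated RNA was in Alexa 647 (red) for replicates 1 to 4 and in Alexa 555 (green) for replicates 5 to 8 of each drug, and 500 ng of total RNA went into each amplification. The series describes the 8 control and the 8 treated cultures as biological replicates.

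The deposited scanner files hold, for each spot, the median pixel intensity of the spot and of its local background in both channels, which the authors left unnormalized. They also hold processed signals in intensity units that Agilent Feature Extraction had background-subtracted, detrended and dye-normalized within the array per the file headers, and a ratio of red over green processed signal on the log10 scale per the file headers. The deposited series table gives 1 value per probe and array on the log2 scale. It was checked against the scanner files and follows the Agilent ratio turned to treated over control, with a correlation over all probes of 0.742 to 0.999 per array. The lowest were SQ1 replicate 5 (0.742) and SQ1 replicate 2 (0.885). Why some arrays correlated less was not tested, so that the check does not show the same values for all probes. The program is named in the submitters' processing notes, and its version, 11.0.1.1, in the file headers. The plan had named the mean spot signal, but the files hold the median only, which was used in its place.

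Median spot and background intensities were read into R 4.3.3 and processed with limma 3.58.1. Background was corrected by normexp with an offset of 50, each array was normalized within itself by loess, and spots of 1 probe were averaged. Of the 44397 spots, 43020 were not controls and represented 39429 probes. The files give no gene names, so probes were named through the RefSeq accession that each carries and the RefSeq mouse annotation. This named 27234 probes for 20659 genes and left 12195 probes without a name. The array design was laid out on an older genome build than the annotation, so no coordinates are given. A probe was tested if it was well above background (the Agilent mark for this) on at least 4 arrays of a drug in the treated channel or in at least 8 control channels, and had a ratio on at least 7 arrays of each drug. The first condition held for 25923 probes and not for 13506. A gene was represented by its probe with the highest mean intensity over the 16 arrays, which left 15053 named genes tested and 5606 genes of the array untested. All 29 entries among the named genes that have another probe went the same way with it.

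The log2 ratio of Alexa 647 over Alexa 555 was fitted with limma (lmFit and eBayes) over all 16 arrays together. Each drug had a coefficient that entered as plus or minus 1 by dye orientation, and a constant column took up the dye effect of each gene, which left 13 residual degrees of freedom. The comparisons were SQ1 against control, pravastatin against control, and SQ1 minus pravastatin. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p of 0.05. The 8 arrays of a drug are described as biological replicates, and these p-values measure spread between arrays taken as independent. Fits with blocks gave correlations of 0.27 between arrays of a slide and 0.47 between arrays of a replicate number. The main fit leaves these out, so that its p-values are not a clean measure of spread between cultures. Errors given after ± are standard errors of the limma fit, and standard deviations (SD) over 8 arrays are of ratios with the dye effect removed. Counts of arrays with the same sign use ratios with the dye effect left in.

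The 18 gene lists, pathways and cell type markers of the liver, were fixed together with the tests, the alternatives and the rule for named genes before the data were examined. They are cholesterol biosynthesis enzymes, sterol-responsive uptake and regulation, fatty acid and triglyceride synthesis, PPARalpha-responsive lipid oxidation, CAR/PXR-responsive drug metabolism, LXR-responsive sterol efflux, bile acid synthesis and transport, NRF2-responsive antioxidant genes, small GTPases and prenylation, actin cytoskeleton and SRF/YAP-responsive genes, hepatocyte-enriched genes, ER stress and integrated stress response, cell cycle, acute phase and inflammation, and markers of Kupffer cells and leukocytes, stellate cells and fibroblasts, endothelium, and cholangiocytes. They hold 350 measured genes, 2 of them in 2 lists. Cyp2b13, Cyp3a41a, Cyp2a5, Ugt1a1, Cyp7a1, Cyp8b1, Slc51a, Gsta1, Cd68, H2-Aa, Vwf and Tff2 were listed but not measured and are not analysed here. Lists were tested with camera (limma) at its preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 18 lists of a comparison, with camera at an estimated correlation and fry beside it.

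Named genes were, for each drug, the 5 largest rises and the 5 largest falls among called genes with the same sign on 8 of 8 arrays, leaving out names that are only clone, LOC, Gm, Rik or accession names, and the 2 members of each list with the smallest adjusted p among those called (4 for the cholesterol, PPARalpha and CAR/PXR lists). Fdft1 was always named. Some genes that qualified are not reported here. For SQ1 minus pravastatin they were the 5 largest differences each way with the same sign in 8 of 8 replicate numbers. Other genes in the text were chosen after their values were seen. Cyp2b, Cyp2c, Cyp3a, Cyp4a, Acot and Mup genes have close relatives whose transcripts can bind the same probe, so that values of single members of these families are uncertain.

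The arrays lie on 4 slides, per the file headers. Slide 1 holds SQ1 replicates 1, 2, 5 and 6, slide 2 SQ1 replicates 3, 4, 7 and 8, and slides 3 and 4 the same numbers of pravastatin. Slide 3 was scanned on 1 day and the others on a later one, and each drug lies on slides of its own. Values within slides were computed with a fit that has a coefficient per slide. Lists were tested within and between slides with camera at the preset correlation only, which does not allow for the larger estimated correlations of many lists. Between 58.9% and 69.6% of probes were well above background in the treated channel and between 59.4% and 68% in the control channel. The median signal over background was 2.75 to 4.18, and 0.483% to 0.858% of spots carried a quality mark.

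The deposited array names carry the same control number on the SQ1 and the pravastatin array of 1 replicate number. This pairing was checked in the data. Control channels were taken as deviations from the mean over the 4 arrays of the same drug and dye orientation. They correlated with that of their own number at 0.659 to 0.855 across probes, higher than with any other number for 8 of 8. Taking off this mean lowers the correlations with other numbers of the same orientation, which favours the own number. Residuals of SQ1 arrays were correlated with those of pravastatin arrays, so that no pair lies on the same slide. Replicate numbers held together on a slide are the same for both drugs and form a group here. The mean correlation was 0.52 within numbers, 0.34 between other numbers of the same group and -0.38 across groups. Of the SQ1 arrays, 3 of 8 correlated best with their own number. The replicate number was left out of the fit, and was tried as a block among the alternatives.

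The alternatives were no background correction, a normexp offset of 0, the Agilent ratio, median centring of each array, the values of the series table, no filter or a strict filter on dim probes, no dye term, only the 8 arrays of 1 drug, the replicate block, slide or scan day as a random block, the mean over probes, all probes, array weights, an adjusted p of 0.01, a fold of at least 1.5, leaving out each array in turn, and the other set tests. Slide as fixed terms, alone and with camera at an estimated correlation, was chosen after seeing the data. Overlap between the drugs was compared with simulated unchanged drugs sharing controls, with turned residuals and with controls split between the drugs. The procedure was tested on simulated data with the residual spread of each gene and noise independent between arrays, which leaves out the likeness of arrays on a slide. It recovered 92% of genes changed by 0.3 on the log2 scale for each drug and 83% for the difference, and 3.45% to 3.94% of its calls were false.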

Results

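Transcript levels were compared between drug-treated and untreated primary mouse hepatocytes on 16 arrays, each of which measured treated and control RNA side by side. SQ1 (100 µM per the labels) was measured on 8 arrays and pravastatin (30 µM) on another 8, after 48 h of treatment. The unit of the SQ1 dose is uncertain, so that the doses differ by an amount that is not known. Both drugs block cholesterol synthesis, at different steps: pravastatin acts near the start of the mevalonate pathway, and SQ1 inhibits squalene synthase, the step that commits farnesyl pyrophosphate to sterols. The comparisons ask what each drug did to the transcripts of the hepatocyte and where the drugs differed. The 15053 named genes tested had a median standard error of 0.04 on the log2 scale for each drug and 0.056 for the difference, and the number of arrays limits the precision.

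SQ1 raised the transcripts of the cholesterol pathway as a group. Fdft1, which encodes squalene synthase, rose 2.09-fold (log2 fold change 1.06 ± 0.09, adjusted p = 4.81e-07, n = 8 arrays). All 20 measured cholesterol biosynthesis enzymes rose, with Lss (lanosterol synthase) at 1.37 ± 0.07, Tm7sf2 at 1.23 ± 0.05 and Hsd17b7 at 1.12 ± 0.05. The list median was 1.06 (SD 0.18 over 8 arrays), above 0 on 8 of 8 arrays, and 20 members rose adjusted over the list alone. Camera gave adjusted p = 5.56e-25, and adjusted p = 0.0624 with an estimated correlation. Of the 13 genes of sterol-responsive uptake and regulation, 11 rose, 1 fell and 1 was not past the threshold, with 11 and 1 adjusted over the list alone. Their median was 0.41, with a camera adjusted p = 5.45e-08 and adjusted p = 0.0624 with an estimated correlation. Lpin1, a phosphatidate phosphatase, rose by 0.79 ± 0.06 and Npc2, which moves cholesterol out of lysosomes, by 0.41 ± 0.03. The member that fell was Scarb1, the receptor for high-density lipoprotein, at -0.17 ± 0.03.

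Genes of fatty acid synthesis, fatty acid oxidation and drug metabolism also rose with SQ1. Acot1, an acyl-CoA thioesterase, had the largest rise among the genes that qualified to be named, 6.24-fold (2.64 ± 0.08, adjusted p = 2.3e-12). It was followed by Fezf1, a transcription factor of the developing forebrain (1.98 ± 0.14), the fatty acid hydroxylase Cyp4a14 (1.96 ± 0.16), the stearoyl-CoA desaturase Scd2 (1.82 ± 0.07) and Cyp2b9 (1.74 ± 0.14). In fatty acid and triglyceride synthesis, 12 of 20 genes rose, 3 fell and 5 were not past the threshold, with 12 and 3 adjusted over the list alone. Their median was 0.31, with a camera adjusted p = 1.83e-05 and adjusted p = 0.311 with an estimated correlation. Scd2 and Acss2, an acetyl-CoA synthetase (1.54 ± 0.09), led the rises, while Scd1, the main desaturase of the adult liver, Srebf1 and Mid1ip1 fell. In PPARalpha-responsive lipid oxidation, 25 of 35 genes rose, 3 fell and 7 were not past the threshold, with 25 and 3 adjusted over the list alone. Their median was 0.39, with a camera adjusted p = 1.58e-12 and adjusted p = 0.216 with an estimated correlation. Beside Acot1, Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 1.38 ± 0.05, Angptl4, an inhibitor of lipoprotein lipase, by 0.64 ± 0.03, and Cyp4a31 by 1.53 ± 0.10. Fgf21 and Vnn1 were among the members that fell. In CAR/PXR-responsive drug metabolism, 18 of 28 genes rose, 1 fell and 9 were not past the threshold, with 18 and 1 adjusted over the list alone. Their median was 0.45, with a camera adjusted p = 3.79e-09 and adjusted p = 0.216 with an estimated correlation. Beside Cyp2b9, Cyp2b10 rose by 1.32 ± 0.12, the P450 reductase Por by 0.60 ± 0.04 and Alas1, the rate-limiting enzyme of haem synthesis, by 0.60 ± 0.05, while Cyp2c50 fell. Of NRF2-responsive antioxidant genes, 9 of 17 rose, with 1 fall and 7 not past the threshold and 9 and 1 adjusted over the list alone. Their median was 0.12, with a camera adjusted p = 0.00102 and adjusted p = 0.216 with an estimated correlation. The list did not pass on slide 1 (median 0.095, camera adjusted p = 0.0942) but did on slide 2 (median 0.24, camera adjusted p = 3.88e-05), and the slides differed (camera adjusted p = 0.0446). The cystine transporter Slc7a11 rose by 0.78 ± 0.09 and the thioredoxin reductase Txnrd1 by 0.34 ± 0.04.

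The falls with SQ1 were led by S100g, a calcium-binding protein, 7.81-fold lower (-2.97 ± 0.18, adjusted p = 5.95e-09, n = 8 arrays). Next were the carbonic anhydrase Car3 (-2.22 ± 0.22), the antimicrobial peptide gene Leap2 (-2.15 ± 0.11), the galactosyltransferase B3galt1 (-1.82 ± 0.18) and the hydroxysteroid dehydrogenase Akr1c6 (-1.79 ± 0.31). All 5 fell further on slide 1 than on slide 2: S100g at -3.28 and -2.65 (adjusted p = 0.0456 for the slides), Car3 at -2.82 and -1.63 (adjusted p = 0.0174), Leap2 at -2.41 and -1.88 (adjusted p = 0.0145), B3galt1 at -2.32 and -1.32 (adjusted p = 0.00421) and Akr1c6 at -2.72 and -0.86 (adjusted p = 0.00139), so that their order depends on the slide. In the cell cycle list, 19 of 20 genes fell and 1 rose, and the same counts held adjusted over the list alone. Their median was -0.48, with a camera adjusted p = 3.65e-09 and adjusted p = 0.216 with an estimated correlation. The median was -0.38 on slide 1 and -0.60 on slide 2 (camera adjusted p = 0.000438 for the slides at the preset correlation). Only 1 of the 20 members differed between the slides past the threshold. Birc5, a mitotic regulator, fell by 0.89 ± 0.13 and Ccne1, the cyclin of S phase entry, by 0.41 ± 0.06, and the riser was Cdkn1a, the inhibitor of cyclin-dependent kinases. In ER stress and integrated stress response, 11 of 18 genes fell, 0 rose and 7 were not past the threshold, and 13 fell adjusted over the list alone. Their median was -0.41, with a camera adjusted p = 2.79e-06 and adjusted p = 0.268 with an estimated correlation. On slide 1 the median was -0.53 with 16 falls and on slide 2 -0.21 with 7 falls (camera adjusted p = 7.65e-05 for the slides). Hspa5, the main chaperone of the endoplasmic reticulum, fell by 0.64 ± 0.05 and Phgdh, an enzyme of serine synthesis, by 0.50 ± 0.07. In acute phase and inflammation, 15 of 20 genes fell, 1 rose and 4 were not past the threshold, with 15 and 1 adjusted over the list alone. Their median was -0.44, with a camera adjusted p = 9.33e-08 and adjusted p = 0.0469 with an estimated correlation. The chemokine gene Cxcl1 fell by 1.05 ± 0.07 and the cytokine gene Il6 by 0.76 ± 0.07, and the member that rose was Cxcl10. With slide terms added after the data were seen, the acute phase call was lost, at adjusted p = 0.0777 with an estimated correlation.

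Markers of Kupffer cells and leukocytes, cells that also express many inflammatory genes, fell beside them: 9 of 17 fell, 1 rose and 7 were not past the threshold, with 9 and 1 adjusted over the list alone. Their median was -0.16, with a camera adjusted p = 1.83e-05 and adjusted p = 0.216 with an estimated correlation. Cd5l, a secreted macrophage protein, fell by 0.79 ± 0.07, Csf1r, the receptor of macrophage colony-stimulating factor, by 0.37 ± 0.03 (lost with median centring), and Cd74 rose. Endothelial markers rose in 6 of 15 cases and fell in 0, with 9 not past the threshold and the same counts adjusted over the list alone. Their median was 0.10, with a camera adjusted p = 0.00264 and adjusted p = 0.311 with an estimated correlation. Among them Lyve1 rose by 0.47 ± 0.08 and the scavenger receptor gene Stab1 by 0.26 ± 0.04.

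Hepatocyte-enriched genes fell with SQ1 on some arrays and not on others. Of 25, 10 fell, 1 rose and 14 were not past the threshold, with 10 and 1 adjusted over the list alone. Their median was -0.25, SD 0.28 over 8 arrays, with a camera adjusted p = 0.00102 and adjusted p = 0.503 with an estimated correlation. It was -0.104 with median centring and -0.375 with scan day as a random block. Fgb, the beta chain of fibrinogen, fell by 0.52 ± 0.06 and Hpd, an enzyme of tyrosine breakdown, by 0.92 ± 0.15 (-1.30 and -0.54 on slides 1 and 2, adjusted p = 0.0331). The list median was -0.42 on slide 1 (camera adjusted p = 1.68e-07) and -0.054 on slide 2 (camera adjusted p = 0.554), and 14 members differed between the slides. Genes of bile acid synthesis and transport shared this split, with a list median of -0.35 on slide 1 (camera adjusted p = 1.54e-06) and 0.076 on slide 2 (camera adjusted p = 0.47). Over both slides, 7 of 18 fell, 1 rose and 10 were not past the threshold, with 7 and 1 adjusted over the list alone. Their median was -0.16, with a camera adjusted p = 0.0355 and adjusted p = 0.665 with an estimated correlation. The receptor Fgfr4 fell by 0.28 ± 0.04 (lost with median centring) and the transporter subunit Slc51b rose by 0.38 ± 0.06. This call was lost without SQ1 replicate 1 (median -0.09, camera adjusted p = 0.177) or without SQ1 replicate 5 (median -0.102, camera adjusted p = 0.123), both on slide 1, and also with array weights (camera adjusted p = 0.0533) and with fry (adjusted p = 0.145).

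A further 5 lists did not pass with SQ1. Of LXR-responsive sterol efflux, 2 of 13 rose, 5 fell and 6 were not past the threshold, with 2 and 5 adjusted over the list alone. Their median was -0.074, 0.04 with median centring, with a camera adjusted p = 0.447. The list passed as lower on slide 1 (median -0.094, camera adjusted p = 0.0321) and not on slide 2 (median 0.051, camera adjusted p = 0.5), and the slides differed (camera adjusted p = 0.000608, 6 members). Pltp, a phospholipid transfer protein, rose by 0.38 ± 0.04 and Abca1, the cholesterol exporter, fell by 0.57 ± 0.07. Of small GTPases and prenylation, 2 of 21 rose, 3 fell and 16 were not past the threshold, with 2 and 3 adjusted over the list alone. Their median was 0.03, with a camera adjusted p = 0.793. Rhoq rose by 0.30 ± 0.04 and Rnd1 fell by 0.17 ± 0.04, a call lost with median centring and with scan day as a random block. Of the actin cytoskeleton and SRF/YAP list, 3 of 24 rose, 7 fell and 14 were not past the threshold, with 3 and 7 adjusted over the list alone. Their median was -0.095, 0.036 with median centring, with a camera adjusted p = 0.12. The list passed without SQ1 replicate 1 (median -0.144, camera adjusted p = 0.0207) and without SQ1 replicate 2 (camera adjusted p = 0.0433). It did not pass on slide 1 (median 0.031, camera adjusted p = 0.214) but fell on slide 2 (median -0.22, 14 of 24 fell, camera adjusted p = 3.52e-06), and the slides differed (camera adjusted p = 3.4e-09, 10 members). Thbs1, a matrix glycoprotein, fell by 0.56 ± 0.09 and Egr1, an immediate early transcription factor, by 0.33 ± 0.05, a call lost with median centring. Of stellate cell and fibroblast markers, 4 of 17 rose, 2 fell and 11 were not past the threshold, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.793). Their median was -0.048, while their mean, 0.046, and the test lay above 0. Lrat, which esterifies retinol, rose by 0.95 ± 0.10 and Pdgfra by 0.33 ± 0.08, a call lost with scan day as a random block. Of cholangiocyte markers, 2 of 11 rose, 3 fell and 6 were not past the threshold, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.54). Their median was 0.01, while their mean, -0.10, and the test lay below 0. The list fell on slide 2 alone (median -0.061, camera adjusted p = 0.0283). Spp1 (osteopontin) fell by 0.65 ± 0.12 and the chloride channel gene Cftr by 0.22 ± 0.05. Both calls were lost with scan day as a random block, and that of Cftr with slide as a random block.

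Across the array, 4860 of 15053 genes (32.3%) differed between SQ1 and control, 2369 higher and 2491 lower, by limma at a Benjamini-Hochberg adjusted p of 0.05. The changes were mostly small: 133 of these genes were at least 1.5-fold higher and 177 at least 1.5-fold lower, and 45 and 39 were at least 2-fold changed. On 8 of 8 arrays, 2659 of the called genes had the same sign. Within slides, 5237 genes were called on slide 1 and 4062 on slide 2, and 1847 differed between the slides. Some lists that rose were higher on slide 2, with medians of 0.91 and 1.17 on slides 1 and 2 for the cholesterol enzymes, 0.24 and 0.51 for the PPARalpha list and 0.14 and 0.67 for the CAR/PXR list. The sterol-responsive list (camera adjusted p = 0.894) and endothelial markers (camera adjusted p = 0.562) did not differ between the slides past the threshold. The count was 2543 with slide as a random block, 2239 with scan day as a random block, 2071 with median centring (71.1% of them higher) and 3121 at an adjusted p of 0.01. With each probe tested by itself it was 7496, of 25826 probes.

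**Figure D1:**
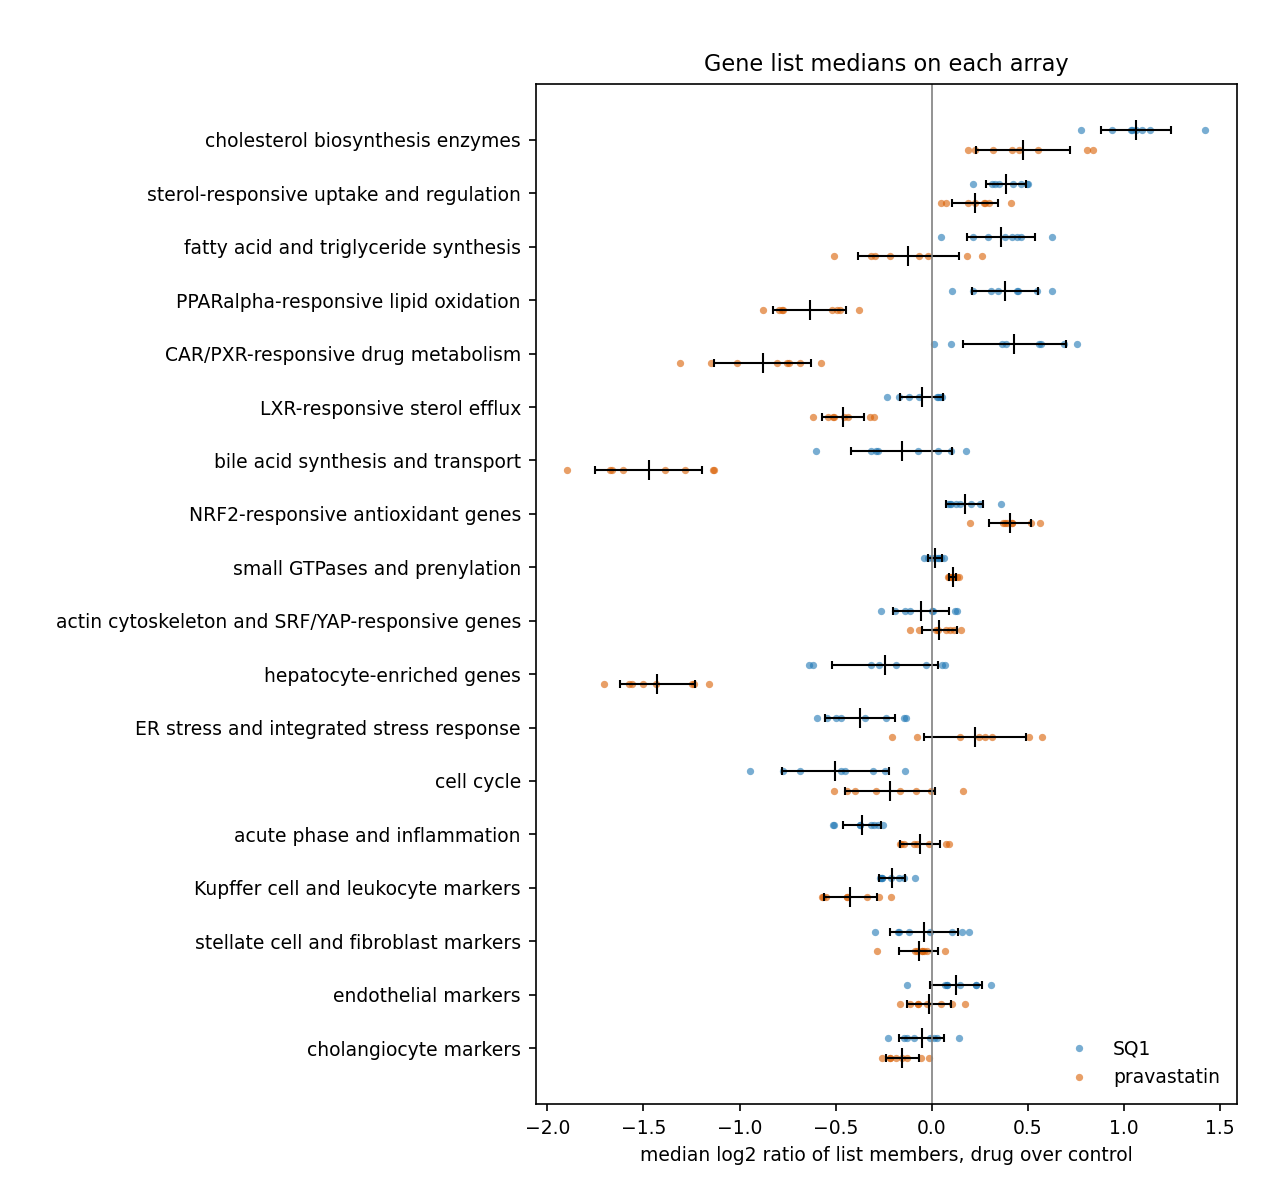
Median log2 fold change of each of the 18 gene lists against untreated control for SQ1 and for pravastatin; points are single arrays (n = 8 per drug) and bars the mean and SD over arrays. The cholesterol biosynthesis enzymes lie above 0 on 8 of 8 arrays of both drugs, whereas the PPARalpha-responsive and CAR/PXR-responsive lists lie above 0 on 8 of 8 SQ1 arrays and below 0 on 8 of 8 pravastatin arrays.

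Pravastatin lowered a broad set of transcripts of the differentiated hepatocyte. Akr1c6 was 50-fold lower (-5.64 ± 0.31, adjusted p = 1.69e-10, n = 8 arrays), followed by Cyp3a11, a main drug-oxidizing P450 (-4.58 ± 0.25), the glucose transporter Slc2a2 (-4.56 ± 0.17), the hepatic uptake transporter Slco1b2 (-4.20 ± 0.27) and Car3 (-4.10 ± 0.22). Akr1c6 fell further on slide 3 than on slide 4 (-6.31 and -4.98, adjusted p = 0.00302 for the slides). So did Slc2a2 (-5.00 and -4.11, adjusted p = 0.0249) and Slco1b2 (-4.90 and -3.51, adjusted p = 0.00269). Cyp3a11 (-4.85 and -4.31, adjusted p = 0.284) and Car3 (-4.39 and -3.81, adjusted p = 0.173) did not differ past the threshold. The order after Akr1c6 depends on the slide. Of hepatocyte-enriched genes, 23 of 25 fell, 0 rose and 2 were not past the threshold, with 23 and 0 adjusted over the list alone. Their median was -1.45, SD 0.19 over 8 arrays, with a camera adjusted p = 2.65e-09 and adjusted p = 0.374 with an estimated correlation. Apoa1, the main protein of high-density lipoprotein, fell by 1.45 ± 0.06 and Serpina1a, an antitrypsin gene, by 1.23 ± 0.05. Foxa2, not past the threshold, was at 0.088 ± 0.045. Of bile acid synthesis and transport, 18 of 18 fell, also adjusted over the list alone. Their median was -1.44, with a camera adjusted p = 3.69e-08 and adjusted p = 0.374 with an estimated correlation. Baat, which conjugates bile acids, fell by 3.66 ± 0.15 and Fgfr4 by 1.07 ± 0.04. Baat was at -4.05 on slide 3 and -3.26 on slide 4 (adjusted p = 0.00402 for the slides), while Fgfr4 did not differ between them (adjusted p = 0.194). Markers of Kupffer cells and leukocytes fell as well, 13 of 17, with 1 rise and 3 not past the threshold and 13 and 1 adjusted over the list alone. Their median was -0.40, with a camera adjusted p = 0.00141 and adjusted p = 0.395 with an estimated correlation. The complement genes C1qa and C1qc fell by 0.86 ± 0.06 and 0.73 ± 0.05, and Cd14 rose.

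Lipid oxidation, drug metabolism and sterol efflux were lower with pravastatin. Of the PPARalpha-responsive genes, 29 of 35 fell, 3 rose and 3 were not past the threshold, with 30 and 3 adjusted over the list alone. Their median was -0.63, with a camera adjusted p = 1.16e-07 and adjusted p = 0.395 with an estimated correlation. It was -0.80 on slide 3 and -0.50 on slide 4 (camera adjusted p = 5.43e-08 for the slides, 21 members). Fabp1, the liver fatty acid-binding protein, fell (-3.53 ± 0.25), as did the transcription factor Creb3l3 (-1.58 ± 0.10) and Angptl4 (-0.53 ± 0.03), whereas Pdk4, Cidec and Aqp7 rose. Fabp1 was at -4.21 on slide 3 and -2.84 on slide 4 (adjusted p = 0.00258 for the slides). Creb3l3 differed too (-1.82 and -1.35, adjusted p = 0.0159), and Angptl4 did not (adjusted p = 0.967). Of the CAR/PXR-responsive genes, 20 of 28 fell, 4 rose and 4 were not past the threshold, with 20 and 4 adjusted over the list alone. Their median was -0.93, with a camera adjusted p = 0.000266 and adjusted p = 0.505 with an estimated correlation. It was -1.09 on slide 3 and -0.70 on slide 4 (camera adjusted p = 0.000309 for the slides, 9 members lower on slide 3 and 1 higher). Nr1i2, which encodes the receptor PXR itself, fell by 1.52 ± 0.07, Aldh1a7 by 1.72 ± 0.09, Cyp2c54 by 1.59 ± 0.07 and Cyp2c29 by 1.36 ± 0.07, whereas Por, Alas1, Abcc2 and Cyp2a4 rose. Of the LXR-responsive genes, 10 of 13 fell, 2 rose and 1 was not past the threshold, with 10 and 2 adjusted over the list alone. Their median was -0.47, with a camera adjusted p = 0.00231 and adjusted p = 0.395 with an estimated correlation. Abca1 fell by 1.78 ± 0.07 and Nr1h3, which encodes the receptor LXRalpha, by 0.71 ± 0.04.

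Transcripts of the cholesterol pathway rose with pravastatin, though not all of them. Fdft1 rose 1.39-fold (0.48 ± 0.09, adjusted p = 0.000264, 7 of 8 arrays), with 0.25 on slide 3 and 0.70 on slide 4 (adjusted p = 0.0302 for the slides). Of the 20 enzymes, 15 rose, 2 fell and 3 were not past the threshold, with 15 and 2 adjusted over the list alone. Their median was 0.47, SD 0.25 over 8 arrays, with a camera adjusted p = 0.00116 and adjusted p = 0.593 with an estimated correlation. Tm7sf2 rose by 0.77 ± 0.05 and Lss by 0.68 ± 0.07, while Ebp, which acts late in the pathway, fell (-0.31 ± 0.05). Acat2, Sc5d and Dhcr7 were at 0.019 ± 0.041, 0.026 ± 0.065 and -0.058 ± 0.091. The list median was 0.27 on slide 3 (camera adjusted p = 0.0358) and 0.66 on slide 4 (camera adjusted p = 4.91e-06), and 11 members differed between the slides. Of sterol-responsive uptake and regulation, 9 of 13 rose, 3 fell and 1 was not past the threshold, with 9 and 3 adjusted over the list alone, but the list missed the threshold (list median 0.30, camera adjusted p = 0.0538) and passed it with the replicate block (camera adjusted p = 0.0494), no filter on dim probes (camera adjusted p = 0.0274), the mean of probes (camera adjusted p = 0.0436), fry (adjusted p = 0.00016), and without SQ1 replicate 4 or pravastatin replicate 1, 3, 5 or 6. Srebf2, the transcription factor of sterol synthesis, rose by 0.72 ± 0.04 and Scarb1 fell by 0.67 ± 0.03.

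The largest rises with pravastatin were of other kinds. The interferon-induced chemokine gene Cxcl10 rose 10.1-fold (3.34 ± 0.18, adjusted p = 1.14e-10, n = 8 arrays) and Slc7a11 7.98-fold (2.996 ± 0.089, adjusted p = 2.67e-13, n = 8 arrays). Others were Glod5 (2.29 ± 0.18) and the interferon-induced antiviral gene Rsad2 (2.13 ± 0.16). Of NRF2-responsive antioxidant genes, 11 of 17 rose, 3 fell and 3 were not past the threshold, with 11 and 3 adjusted over the list alone. Their median was 0.42, with a camera adjusted p = 0.00132 and adjusted p = 0.374 with an estimated correlation. Beside Slc7a11, Txnrd1 rose by 1.03 ± 0.04, and Gstm1, Ephx1 and Mgst1 were the members that fell.

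The other 9 lists did not pass with pravastatin, although single members changed both ways. Of small GTPases and prenylation, 11 of 21 rose, 5 fell and 5 were not past the threshold, with 12 and 5 adjusted over the list alone. Their median was 0.11, with a camera adjusted p = 0.0808. The list passed with median centring (median 0.28, camera adjusted p = 0.0114), with no filter on dim probes (camera adjusted p = 0.0489) and with fry (adjusted p = 6.12e-08). Rhoq rose by 0.64 ± 0.04 and Ggps1, the synthase of geranylgeranyl pyrophosphate, by 0.31 ± 0.03. Of fatty acid and triglyceride synthesis, 6 of 20 rose, 8 fell and 6 were not past the threshold, with 6 and 8 adjusted over the list alone. Their median was -0.12, with a camera adjusted p = 0.727. It was -0.28 with 11 falls on slide 3 and 0.063 with 8 rises on slide 4, and the slides differed (camera adjusted p = 9.59e-05, 10 members). Scd2 rose by 1.54 ± 0.07 while Scd1 fell by 1.95 ± 0.14. Of ER stress and integrated stress response, 10 of 18 rose, 7 fell and 1 was not past the threshold, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.739); the median, 0.26, and the test lay above 0 and the mean, -0.019, below. The median was 0.049 on slide 3 and 0.42 on slide 4 (camera adjusted p = 2.94e-06 for the slides, 13 members lower on slide 3 and 1 higher). Eif4ebp1, a repressor of translation, rose by 0.58 ± 0.05, with Ddit3, Trib3 and Atf3, while Hspa5 fell by 0.89 ± 0.05, with Herpud1, Dnajb9 and Xbp1. Of the actin list, 9 of 24 rose, 8 fell and 7 were not past the threshold, with 9 and 8 adjusted over the list alone (camera adjusted p = 0.744); the median, 0.04, and the test lay above 0 and the mean, -0.13, below. The transcription factor Klf4 rose by 1.19 ± 0.08 and the smooth muscle gene Cnn1 fell by 1.82 ± 0.10. Of acute phase and inflammation, 6 of 20 rose, 8 fell and 6 were not past the threshold, with 6 and 8 adjusted over the list alone. Their median was -0.063, 0.035 with median centring, with a camera adjusted p = 0.744, and the list passed with fry (adjusted p = 0.000641). Crp fell by 2.04 ± 0.09 and Hp (haptoglobin) by 1.14 ± 0.06.

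In the cell cycle list with pravastatin, 1 of 20 rose, 10 fell and 9 were not past the threshold, with 1 and 9 adjusted over the list alone. Their median was -0.22, with a camera adjusted p = 0.394. It was -0.09 on slide 3, with 2 rises and 1 fall, and -0.34 on slide 4, with 1 rise and 11 falls. The slides differed (camera adjusted p = 0.000627, 2 members). Ccna2 fell by 0.48 ± 0.12 and Ccne1 by 0.41 ± 0.06. Stellate cell and fibroblast markers had 3 of 17 rises, 5 falls and 9 not past the threshold, with 3 and 5 adjusted over the list alone. Their median was -0.10, 0.007 with median centring, with a camera adjusted p = 0.744. Timp1, an inhibitor of metalloproteinases, rose by 0.72 ± 0.10 and the matrix proteoglycan gene Dcn fell by 0.27 ± 0.05, a call lost with median centring. Among endothelial markers, 4 of 15 rose, 5 fell and 6 were not past the threshold, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.966); the median, 0.042, and the test lay above 0 and the mean, -0.05, below. Stab2 fell by 0.59 ± 0.06 and Lyve1 by 0.48 ± 0.08. Cholangiocyte markers had 3 of 11 rises, 5 falls and 3 not past the threshold, with 3 and 5 adjusted over the list alone. Their median was -0.19, with a camera adjusted p = 0.744. The claudin gene Cldn4 rose by 0.94 ± 0.08.

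By limma and Benjamini-Hochberg, 10041 of 15053 genes (66.7%) differed between pravastatin and control, 4648 higher and 5393 lower. Of these, 441 were at least 1.5-fold higher and 1255 at least 1.5-fold lower, 131 and 604 were at least 2-fold changed, and 6514 had the same sign on 8 of 8 arrays. Within slides, 9684 genes were called on slide 3 and 8649 on slide 4, and 3275 differed between the slides. The count was 8262 with slide as a random block, 8314 with scan day as a random block and 7171 with median centring. With the Agilent ratio 56.8% of the called genes were higher and with median centring 61%, in place of 46.3%. Tested 1 by 1, 16476 of 25826 probes were called.

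The direct comparison asked where the effects of the drugs differed. All 20 cholesterol biosynthesis enzymes were higher with SQ1 than with pravastatin, also adjusted over the list alone. Their median difference was 0.61, SD 0.16 over 8 replicate numbers, with a camera adjusted p = 4.1e-07 and adjusted p = 0.317 with an estimated correlation. The difference was 0.40 ± 0.14 for Cyp51, the smallest of the list, and 0.58 ± 0.13 for Fdft1. The largest differences were in drug metabolism and fatty acid binding. Cyp3a11 was 28-fold higher with SQ1 than with pravastatin (4.81 ± 0.35, adjusted p = 1.91e-08, the same sign in 8 of 8 replicate numbers), and Fabp1 was 22.3-fold higher (4.48 ± 0.35). Cyp3a59 (4.43 ± 0.28), Cyp3a25 (4.38 ± 0.40) and Cyp3a41b (4.19 ± 0.29) came next, relatives of Cyp3a11 that its probe and theirs may not tell apart. For Cyp3a11 and Cyp3a25 the SQ1 values themselves, 0.23 ± 0.25 and 0.41 ± 0.28, were not past the threshold, and average opposite signs on slides 1 and 2: -0.46 and 0.91 for Cyp3a11 (adjusted p = 0.0179 for the slides) and -0.43 and 1.26 for Cyp3a25 (adjusted p = 0.000987). On the other side were Glod5 (-3.18 ± 0.25), Cxcl10 (-2.82 ± 0.25), Serpinb2, an inhibitor of plasminogen activators (-2.34 ± 0.16), and Slc7a11 (-2.22 ± 0.13), lower with SQ1.

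The lists of lipid oxidation and drug metabolism moved in opposite directions with the drugs. Of the 35 PPARalpha-responsive genes, 33 were higher with SQ1 than with pravastatin, 1 was lower and 1 was not past the threshold, with 34 and 1 adjusted over the list alone. The median of their differences was 1.11, with a camera adjusted p = 5.77e-16 and adjusted p = 0.256 with an estimated correlation. Of the 28 CAR/PXR-responsive genes, 23 were higher, 0 lower and 5 not past the threshold, with 25 and 0 adjusted over the list alone. These had a median difference of 1.44, with a camera adjusted p = 4.54e-11 and adjusted p = 0.256 with an estimated correlation. Of hepatocyte-enriched genes, 21 of 25 were higher with SQ1, 0 lower and 4 not past the threshold, with 23 and 0 adjusted over the list alone. The difference had a list median of 1.24, with a camera adjusted p = 7.16e-10 and adjusted p = 0.256 with an estimated correlation. Arg1 (arginase) was higher by 3.56 ± 0.33. Of bile acid synthesis and transport, 16 of 18 were higher, 0 lower and 2 not past the threshold, also adjusted over the list alone. Their median difference was 1.34, with a camera adjusted p = 1.39e-08 and adjusted p = 0.256 with an estimated correlation. For Baat the difference was 3.32 ± 0.22. Fatty acid and triglyceride synthesis had 15 of 20 higher, 0 lower and 5 not past the threshold, also adjusted over the list alone. The median of their differences was 0.39, with a camera adjusted p = 6.98e-05 and adjusted p = 0.377 with an estimated correlation. For Gpam the difference was 1.23 ± 0.10. LXR-responsive sterol efflux had 10 of 13 higher, 2 lower and 1 not past the threshold, with 10 and 2 adjusted over the list alone. These had a median difference of 0.40, with a camera adjusted p = 0.00198 and adjusted p = 0.256 with an estimated correlation. For Abca1 the difference was 1.21 ± 0.09.

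A further 4 lists passed as lower with SQ1 than with pravastatin, all with members that did not differ or, except for the cell cycle list, were higher, and none passed with an estimated correlation. Of NRF2-responsive genes, 3 of 17 were higher, 10 lower and 4 not past the threshold, with 3 and 10 adjusted over the list alone. The difference had a list median of -0.36, with a camera adjusted p = 0.00517 and adjusted p = 0.256 with an estimated correlation. For Gclc the difference was -0.85 ± 0.12. In ER stress and integrated stress response, 4 of 18 were higher, 10 lower and 4 not past the threshold, with 4 and 10 adjusted over the list alone. Their median difference was -0.51, with a camera adjusted p = 0.0136 and adjusted p = 0.569 with an estimated correlation. Ddit3, a transcription factor of the stress response, differed by -1.39 ± 0.20, and the list call was lost with the Agilent ratio (camera adjusted p = 0.0626) and with the values of the series table (camera adjusted p = 0.0618). Cell cycle genes were higher in 0 of 20 cases, lower in 7 and not past the threshold in 13, with 0 and 6 adjusted over the list alone. The median of their differences was -0.31, with a camera adjusted p = 0.00492 and adjusted p = 0.569 with an estimated correlation. For Pcna the difference was -0.42 ± 0.08. In acute phase and inflammation, 5 of 20 were higher, 11 lower and 4 not past the threshold, with 5 and 12 adjusted over the list alone. These had a median difference of -0.34, with a camera adjusted p = 0.0136 and adjusted p = 0.256 with an estimated correlation. For Cxcl2 the difference was -1.02 ± 0.09; the list call was lost with the strict filter (camera adjusted p = 0.0528).

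The remaining 7 lists did not pass the test of the difference. Sterol-responsive uptake and regulation had 6 of 13 higher with SQ1, 1 lower and 6 not past the threshold, with 6 and 2 adjusted over the list alone. The difference had a list median of 0.15, with a camera adjusted p = 0.151. Small GTPases and prenylation had 4 of 21 higher, 11 lower and 6 not past the threshold, with 4 and 11 adjusted over the list alone. Their median difference was -0.16, with a camera adjusted p = 0.0566. The list passed with median centring (camera adjusted p = 0.0469), no filter on dim probes (camera adjusted p = 0.0345), the mean of probes (camera adjusted p = 0.0462) and fry (adjusted p = 9.57e-06), and without SQ1 replicate 6 or pravastatin replicate 1 or 8. The actin list had 5 of 24 higher, 9 lower and 10 not past the threshold, with 5 and 9 adjusted over the list alone (camera adjusted p = 0.294); the median difference, -0.065, and the test lay below 0 and the mean, 0.009, above. Markers of Kupffer cells and leukocytes had 7 of 17 higher, 3 lower and 7 not past the threshold, with 7 and 3 adjusted over the list alone (median difference 0.098, camera adjusted p = 0.279), stellate cell and fibroblast markers 5 of 17, 3 and 9, with 5 and 3 adjusted over the list alone (0.082, camera adjusted p = 0.625), and endothelial markers 5 of 15, 0 and 10, with 4 and 0 adjusted over the list alone (0.18, camera adjusted p = 0.115). Endothelial markers passed with scan day as a random block (camera adjusted p = 0.0365) and fry (adjusted p = 0.00863), and with fry so did the sterol-responsive list (adjusted p = 0.0012) and markers of Kupffer cells and leukocytes (adjusted p = 0.0101). Cholangiocyte markers had 3 of 11 higher, 3 lower and 5 not past the threshold, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.92); the median difference was 0.045, while the mean, -0.026, and the test lay below 0.

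By limma and Benjamini-Hochberg, 7996 of 15053 genes (53.1%) differed between the effects of the drugs, 4407 higher with SQ1 and 3589 lower. Of these, 1166 were at least 1.5-fold higher and 462 at least 1.5-fold lower, and 6670 had the same sign in 8 of 8 replicate numbers. The drugs lie on different slides and differ in labelled dose, so that neither can be separated from the drug in this comparison beyond the fact that each array carries its own control. The comparison of slide 1 with slide 3 called 6978 genes and that of slide 2 with slide 4 called 6866, and the cholesterol list differed by 0.72 and 0.53. The count was 5716 with slide as a random block, 7168 with scan day as a random block and 3697 with median centring. It was 9412 with replicate numbers as a paired block and 12582 of 25826 with each probe tested by itself. With the Agilent ratio 44.7% of the called genes were higher with SQ1 in place of 55.1%.

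**Figure D2:**
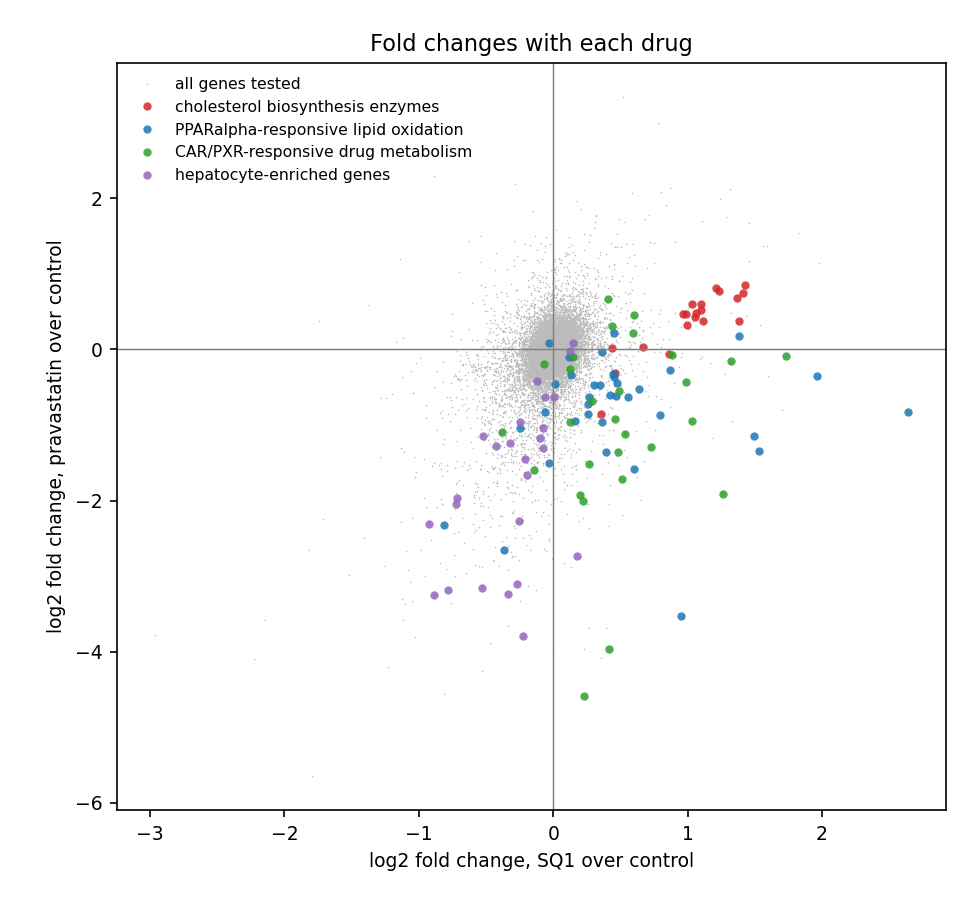
Log2 fold change with SQ1 (x axis) against that with pravastatin (y axis) for the 15053 genes tested, each a point, against untreated control (n = 8 arrays per drug). Across genes the effects correlated at r = 0.377, with 1245 genes called higher and 1490 called lower with both drugs.

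The overlap of the effects was measured because the arrays of 1 replicate number can carry the same control RNA, which by itself makes the effects of unrelated drugs alike. Across genes, which are not independent replicates, the log2 fold changes of the drugs correlated at r = 0.377, with a covariance of 0.0364. Both drugs called 3691 genes, of which 2735 (74.1%) went the same way: 1245 higher and 1490 lower with both, where independent calls would give 731 and 892. Another 541 genes were higher with SQ1 and lower with pravastatin, and 415 the reverse, where independent calls would give 849 and 769. With controls split between the drugs, r averaged 0.343 over 36 splits (0.002 to 0.552) and the covariance 0.034. Simulated unchanged drugs with shared controls gave r = 0.498 but a covariance of 0.0016 and 0 genes called by both. Unchanged drugs made from the real residuals gave a mean covariance of 0.00286 over 18 arrangements, with 39 genes called higher and 88 called lower with both. The arrangement that followed the slides gave a covariance of 0.0114, below the measured 0.0364. It had 690 genes called higher, 1581 called lower and 2 called in opposite directions. The sign of this arrangement is a choice, and turning it swaps 690 and 1581. These counts therefore cannot be set against the shared rise (1245 genes) or the shared fall (1490 genes) by direction. The arrangement also makes the slide difference the whole effect, whereas each drug was measured on 2 slides. A slide difference that stands in for the drug can thus give many shared calls. Whether these are the genes shared by the drugs was not tested. Per replicate number, r ran from 0.11 to 0.791.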

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

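The tests of the slides and of other cell types were chosen only after the results they bear on were seen; the other tests in this part were not. Of 138 groups of 8 arrays that were checked for 1 array far from the rest, 4 held such an array, where chance alone gives about 1 in 20. Pltp rose with SQ1 by 0.32 to 0.5 on 7 arrays but by 0.08 on replicate 1. The median of stellate cell and fibroblast markers was -0.29 on pravastatin replicate 2 and -0.08 to 0.07 on the others. Srebf2 was at 0.93 on pravastatin replicate 7 and at 0.65 to 0.76 on the others. Stab2 was at -0.29 on pravastatin replicate 6 and at -0.72 to -0.53 on the others. Among the gene lists, 2 passed in opposite directions with the drugs and in the test of the difference: PPARalpha-responsive lipid oxidation, with a median difference of 1.112 (camera adjusted p = 5.77e-16, adjusted p = 0.256 with an estimated correlation), and CAR/PXR-responsive drug metabolism, with 1.437 (camera adjusted p = 4.54e-11, adjusted p = 0.256 with an estimated correlation). Hepatocyte-enriched genes had a median difference of 1.242 and fell further with pravastatin (-1.452) than these lists (-0.632 and -0.932). With SQ1 they were at -0.247, while these lists rose. How far the falls with pravastatin are particular to the 2 lists was not tested.

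The fall of hepatocyte-enriched genes with SQ1 differed between replicates, with list medians from -0.64 to 0.069. The SD over the 8 arrays with the Agilent ratio was 0.967 of that with loess, which argues against the loess fit as the source. The Agilent ratio is itself dye-normalized within the array, so that normalization within arrays in general stays open. A difference between slides had the values it needs: the mean of slide 2 exceeded that of slide 1 by 0.438 (-0.024 against -0.462, exact permutation p = 0.0286 over 70 splits), and the 2 slides also carry different cultures, so that slide and culture cannot be told apart. The pravastatin arrays of the same replicate numbers, on slides 3 and 4, split alike. Slide 3 minus slide 4 was -0.437 for hepatocyte-enriched genes (camera adjusted p = 2.05e-05, 12 members) against -0.443 for slide 1 minus slide 2. For the bile acid list it was -0.537 against -0.521. The split is thus not particular to SQ1 and goes along with the replicate numbers, which by name share control RNA. It also goes along with the spike-in signal, with array medians of 6052 to 10983.5 on slides 1 and 3 and 2017 to 3418 on slides 2 and 4. A difference in array handling common to both drugs therefore cannot be told apart from culture or control RNA. Control RNAs that differ stay open too: over the 8 replicate numbers the SQ1 list median correlated with the control level on the pravastatin array at r = -0.807 (exact permutation within dye orientations p = 0.023, adjusted p = 0.0451 over 2 relations; rho = -0.643, p = 0.101), but r was -0.339 without the 2 numbers farthest from the median, so that it rests on those, and a slide has only 4 arrays to test it in. No biological explanation was tested, since the design names no difference among the replicates.

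Hepatocyte-enriched genes fell with pravastatin, with a list median of -1.452. A lower share of hepatocytes raises the markers of every other cell type, if the drug does not change those markers itself. Over 60 markers of 4 other cell types the median was -0.114 (SD 0.065 over 8 arrays), -0.03 with median centring. List medians were -0.401 for Kupffer cells and leukocytes, -0.101 for stellate cells and fibroblasts, 0.042 for endothelium and -0.193 for cholangiocytes. These values argue against a lower share as the only change. A lower share together with an effect of the drug on the markers was not tested. The tables also argue against the loess normalization as the source, since the list median was -1.224 with median centring and -1.464 with the Agilent ratio. An effect of pravastatin on the hepatocytes at this dose is consistent with these values as a hypothesis; whether it follows from less sterol, from less of the other products of the pathway or from harm to the cells was not tested.

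Cholesterol biosynthesis enzymes rose further with SQ1 than with pravastatin. The tables argue against the loess normalization as the source, since the median difference was 0.557 with the Agilent ratio and 0.572 with median centring. The general fall of hepatocyte transcripts with pravastatin stays open as a candidate explanation: over the 8 replicate numbers the differences in both lists correlated at r = -0.267 (exact permutation within dye orientations p = 0.293, adjusted p = 0.293; rho = -0.333, p = 0.351; r = -0.019 without the 2 numbers farthest from the median), and 8 numbers are too few to decide. The drugs differ in labelled dose, with the SQ1 unit uncertain, and lie on different slides, and a difference between the drugs as such stays among the open explanations.

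Chance was tested for the 3 counts by regrouping the arrays. For SQ1, 1 of 35 splits of the dye orientations, the real one with 4860 genes, gave as many, and the highest of the others gave 0. For pravastatin, 1 of 35 did, the real one with 10041 genes, and the highest of the others gave 23. For the difference, 1 of 100 splits did, the real one with 7996 genes. Of the 100, 50 part all 8 pairs of replicate numbers like the real one, with a highest other of 5011, while those that do not part all pairs reached 3210 and the split along the slides called 1131. At the level of these splits the values argue against chance as the source of the 3 counts, with 1 of 35 the lowest share possible for a drug. In every other split a real drug effect stays in the residuals, which lowers the count. Splits of the difference that exchange few pairs keep most arrays with their own drug, so that their counts hold a part of the drug difference. How large a part of the 5011 genes this makes up was not tested.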

How the results depend on the processing

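Slide as fixed terms was chosen after seeing the data, the other alternatives before. Of 954 values of the 54 list results under other settings, 856 kept their direction and their side of the threshold, 68 lost the call, 16 gained it and 14, all of lists without a call, changed sign; of 1782 values of named genes 1772 kept both and 10 lost the call: Fgfr4, Rnd1, Egr1 and Csf1r with SQ1 and Dcn with pravastatin under median centring, Rnd1, Pdgfra, Spp1 and Cftr with SQ1 under scan day as a random block, and Cftr under slide as a random block. The count for SQ1 was 2071 with median centring, 2543 with slide and 2239 with scan day as a random block, 3121 at an adjusted p of 0.01 and 310 with a fold of at least 1.5. With that fold pravastatin had 1696 genes and the difference 1628, and with median centring they had 7171 and 3697. With slide as a random block they had 8262 and 5716, and with scan day as a random block 8314 and 7168. With all probes the counts were 7496, 16476 and 12582, since more features are tested. A stricter threshold lowers a count by construction; for the other settings the cause was not tested. Fitting only the drug's 8 arrays gives no test of the difference, which was not run there. Leaving out 1 array gave 4051 to 5104 genes for SQ1, 9612 to 10045 for pravastatin and 7480 to 8273 for the difference. With the replicate block, counts were 4725, 9869 and 9412, the last as a paired fit, and with slide as fixed terms 6157, 10586 and 8809.

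With an estimated correlation, 1, 0 and 0 lists passed for SQ1, pravastatin and the difference, since a positive estimated correlation above the preset widens the test. With slide terms as well, 0, 0 and 0 passed; the loss of the acute phase list (adjusted p = 0.0777 in place of 0.0469) came with a lower estimated correlation (0.074 in place of 0.086), and its cause was not tested. The medians stayed in place, here with adjusted p without and with slide terms: cholesterol enzymes 1.057 (0.0624, 0.0777), 0.465 (0.593, 0.54) and 0.605 (0.317, 0.33); PPARalpha list 0.391 (0.216, 0.0802), -0.632 (0.395, 0.217) and 1.112 (0.256, 0.0807); CAR/PXR list 0.447 (0.216, 0.0777), -0.932 (0.505, 0.336) and 1.437 (0.256, 0.0807); hepatocyte-enriched genes -0.247 (0.503, 0.33), -1.452 (0.374, 0.213) and 1.242 (0.256, 0.126). The lists that changed sign were not past the threshold before or after. The result cholangiocyte markers, SQ1 went from 0.01 to -0.03 with no background correction, -0.101 with the Agilent ratio and with the series table, -0.034 with median centring, -0.187 with the strict filter, -0.009 with array weights and -0.016 to 0.018 without 1 SQ1 array (below 0 without replicate 1, 2 or 5). The result cholangiocyte markers, difference went from 0.045 to -0.017 with median centring, -0.022 with array weights and -0.034 to 0.104 without 1 array (below 0 without SQ1 replicate 1 or pravastatin replicate 4). With median centring the LXR list was at 0.04, the actin list at 0.036 and stellate cell markers at 0.051 with SQ1, and the acute phase list at 0.035 and stellate cell markers at 0.007 with pravastatin. The result stellate cell and fibroblast markers, SQ1 was at 0.014 with scan day as a block and at -0.083 to 0.007 without 1 array (above 0 without SQ1 replicate 6). The cause of these changes was not tested. Signal over background (2.75 to 4.18) limits dim genes, and the 13506 probes below the rule for dim probes were not tested.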

Other observations

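The gene families and single genes in this part were chosen after their values were seen, from 372 families screened by symbol. Unless said otherwise, adjusted p-values of families in this part are over the chosen families of a comparison only. They are therefore lower than an adjustment over all families screened would give. With pravastatin, interferon-stimulated genes other than Cxcl10 rose as well: beside Rsad2 (2.13 ± 0.16), these were Oasl1 (1.12 ± 0.09), Ifit1 (1.097 ± 0.224), Oasl2 (1.07 ± 0.10), Ifit3 (0.97 ± 0.17), Usp18 (0.84 ± 0.08), Isg15 (0.74 ± 0.09) and Gbp2 (0.73 ± 0.06). These were picked for their values with pravastatin. With SQ1, 7 of these 8 were called higher as well: Rsad2 (0.87 ± 0.16), Ifit1 (0.61 ± 0.22), Ifit3 (0.51 ± 0.17), Oasl1 (0.45 ± 0.09), Usp18 (0.38 ± 0.08), Oasl2 (0.30 ± 0.10) and Gbp2 (0.18 ± 0.06). Isg15 (0.21 ± 0.10) was not past the threshold. In the test of the difference, Rsad2 (-1.26 ± 0.23, adjusted p = 0.000243), Oasl1 (adjusted p = 0.000272), Oasl2 (adjusted p = 0.000229), Usp18 (adjusted p = 0.00411), Isg15 (adjusted p = 0.00309) and Gbp2 (adjusted p = 2.07e-05) were lower with SQ1, while Ifit1 (adjusted p = 0.21), Ifit3 (adjusted p = 0.127) and Irf7 (adjusted p = 0.212) were not past the threshold. Ifit2 went the other way, at 0.33 ± 0.07 with SQ1 and -0.004 ± 0.074 with pravastatin (adjusted p = 0.0131 for the difference), and Cxcl9 was at 0.26 ± 0.07 and 0.18 ± 0.07 (adjusted p = 0.548 for the difference). Ribosomal protein transcripts rose with pravastatin, 41 of 46 for the large subunit (median 0.20, 1 fell) and 26 of 30 for the small subunit (median 0.20, 0 fell), at camera adjusted p = 2.07e-09 and 1.41e-07, and adjusted p = 0.147 with an estimated correlation for both. Subunits of mitochondrial complex I fell with pravastatin in 35 of 36 cases and rose in 1 (median -0.34, camera adjusted p = 9.05e-10, adjusted p = 0.147 with an estimated correlation), cytochrome c oxidase subunits in 11 of 12 (median -0.29, camera adjusted p = 0.000739, adjusted p = 0.158 with an estimated correlation) and peroxins, which build peroxisomes, in 15 of 16 (median -0.36, camera adjusted p = 4.85e-05, adjusted p = 0.259 with an estimated correlation). The directions held with the Agilent ratio, median centring and no background correction, but the sizes did not: with median centring the medians were 0.419 and 0.412 for the ribosomal subunits, -0.16 for complex I, -0.075 for cytochrome c oxidase and -0.217 for peroxins, whereas with SQ1 the medians of the last 3 families, -0.043, -0.056 and -0.022, turned to 0.082, 0.081 and 0.093 with median centring.

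With SQ1, 12 of 17 subunits of the vacuolar ATPase, the proton pump of lysosomes, rose and 0 fell (median 0.17, above 0 on 8 of 8 arrays, camera adjusted p = 2.29e-06, adjusted p = 0.0117 with an estimated correlation), and with pravastatin 6 rose and 4 fell (median 0.069, camera adjusted p = 0.429; 0.159 with the Agilent ratio and 0.184 with median centring, against 0.177 and 0.29 for SQ1). Over the 372 families screened the rise with SQ1 had a camera adjusted p = 7.76e-05. The test with an estimated correlation was run on the chosen families only, so that its 0.0117 does not allow for the screen. The difference had 7 of 17 higher with SQ1 and 0 lower (median 0.105, 0.037 with the Agilent ratio and 0.082 with median centring, camera adjusted p = 0.0329, adjusted p = 0.16 with an estimated correlation), so that its size depends on the scaling. Over all families screened this difference was not past the threshold. The 6 subunits of the MCM helicase, which opens DNA for replication, fell with SQ1 (median -0.40, camera adjusted p = 0.000415, adjusted p = 0.241 with an estimated correlation), and were lower with SQ1 than with pravastatin by a median of -0.39 (camera adjusted p = 0.00584, adjusted p = 0.222 with an estimated correlation). Host genes of small nucleolar RNAs fell with SQ1 in 8 of 10 cases (median -0.36, camera adjusted p = 5.16e-06, adjusted p = 0.124 with an estimated correlation), while with pravastatin 6 rose and 1 fell (median 0.19, camera adjusted p = 0.0286, adjusted p = 0.326 with an estimated correlation). Over the 372 families screened, their fall with SQ1 had a camera adjusted p = 0.000131, and their rise with pravastatin was not past the threshold. Sult2a sulfotransferases, which conjugate steroids and bile acids and resemble each other closely, rose with SQ1 in 5 of 6 cases (median 0.75, 1.69 with the Agilent ratio, camera adjusted p = 0.000342, or 0.00818 over all families screened, adjusted p = 0.212 with an estimated correlation). Major urinary protein transcripts, also near-identical, fell in 10 of 10 cases with SQ1 (median -0.40, camera adjusted p = 3.62e-07, adjusted p = 0.155 with an estimated correlation) and in 10 of 10 with pravastatin (median -0.97, camera adjusted p = 2.61e-06, adjusted p = 0.147 with an estimated correlation).

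In all, 956 genes were called in opposite directions with the drugs, 541 of them higher with SQ1. Among them were Retsat, which reduces retinol (0.87 ± 0.09 with SQ1, -0.77 ± 0.09 with pravastatin), Adtrp (0.69 ± 0.08, -0.95 ± 0.08), Slc16a12 (0.68 ± 0.10, -1.47 ± 0.10) and the growth factor gene Areg (-0.70 ± 0.12, 1.03 ± 0.12). Of 6106 tested probes without a gene name, 1290 (21.1%) differed from control with SQ1, 3529 (57.8%) with pravastatin and 2520 (41.3%) between the drugs. Spike-in transcripts were brighter on slides 1 and 3, with array medians of 6052 to 10983.5, than on slides 2 and 4, with 2017 to 3418.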
